A study of Mus musculus with 12 samples.

How the data were processed

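Read counts per gene were analysed for 12 libraries of C2C12 cells, 3 in each of 4 groups, control or Cebpg knockdown with DMSO or thapsigargin for 6 h. Per the submitters' processing notes, the authors selected poly(A) RNA, trimmed reads with Trim Galore, aligned them with STAR 2.5.3a, used bedtools 2.31.0 and deposited raw counts per gene. The notes name DESeq2 and both the mm10 and hg38 builds. The counter, the annotation release and the strand of the libraries were not given in the sources used here, so genes that overlap or lie antisense to others are uncertain.

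The deposited counts held 53801 gene identifiers and 5 further entries that name no gene, which held 13.32% to 14.61% of reads per library. Of the identifiers 53706 were matched to GENCODE vM21 on GRCm38 and 95 were not, the latter holding at most 0.0031% of the reads of any library. A symbol was shared by 203 genes. Libraries held 29.42 to 47.72 M gene reads.

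Tests used edgeR 4.0.16 with TMM scaling, its filter for low counts and robust quasi-likelihood fits over the 4 groups, with 8 residual degrees of freedom and a common biological coefficient of variation of 4.67%. The filter left 15828 genes tested and 37973 not tested. Adjusted p-values are those of Benjamini and Hochberg, with calls under 0.05. Each SE given is the absolute log2 change divided by the square root of its F statistic. It is therefore approximate, and not an SE taken from the fit. The 5 comparisons were the knockdown in each treatment, thapsigargin in each cell population, and the difference of the thapsigargin effects. Genes named in the text were the 6 largest changes in each direction with a group mean of at least 5 CPM and no overlap of libraries, with members of the lists. Results of some genes are not reported.

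The 28 gene lists, with 485 entries, were written before the data were examined and tested with camera of limma 3.58.1 at a preset correlation of 0.01, and again with an estimated one. They covered ATF4 and CHOP stress regulators, amino acid synthesis and one-carbon metabolism, amino acid transporters, cytosolic aminoacyl-tRNA synthetases with the exportin gene Xpot, ER chaperones, ER-associated degradation and the secretory pathway, glutathione and NRF2, cholesterol synthesis, S phase, G2 and mitosis, myogenic regulators, muscle differentiation, the C/EBP and ATF family and immediate early genes. They also covered inflammatory, interferon, p53, autophagy, heat shock, mitochondrial unfolded protein, glycolysis, matrix, ribosomal and mitochondrially encoded genes, and leukocyte, epithelial, endothelial and adipocyte markers. A list needed 5 tested members, which left 135 tests.

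The pipeline was tested on simulated data. It recovered 97% of genes given a log2 change of 1 and 83% of those given 0.5 for the knockdown in DMSO, and 97% and 76% for the difference of effects. False calls numbered 9 and 5. The genes changed had a mean of at least 1 CPM, 100 of each size per comparison, and nearly all other genes were left unchanged. Simulated counts took their spread from the fitted trend, not from each gene, and held no general thapsigargin effect. The rates therefore do not cover genes below 1 CPM, genes that vary more than the trend, or data in which as many genes change as here. Alternatives were other scalings, filters and thresholds, DESeq2 1.42.0, limma-voom, a replicate block, removal of GC and exon length trends, other list tests and leaving out each library. The software was R 4.3.3, Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.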

Results

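Messenger RNA was sequenced from C2C12 cells, a mouse myoblast line that can form muscle fibres in culture. The design crossed control cells and cells with Cebpg knocked down with 6 h of DMSO, the solvent, or of thapsigargin. Thapsigargin inhibits the SERCA calcium pump, empties the calcium store of the endoplasmic reticulum (ER) and causes ER stress. The sample titles name the knockdown only as Sh2, a single label, and what the control cells received is not given in the sources used here. An effect of the knockdown can therefore not be told from an off-target effect, or from another lasting difference between the cell populations. The growth protocol names HeLa cells, whereas the source field names C2C12. Each of the 4 groups held 3 libraries, 12 in all. Reads assigned to genes numbered 34.4, 35.3 and 34.7 M in control DMSO replicates 1 to 3. With thapsigargin the control replicates held 32.1, 47.7 and 36.7 M. The knockdown replicates held 31.7, 35.1 and 34.9 M in DMSO and 32, 29.4 and 31.7 M with thapsigargin. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these libraries. Replicates differed by more than counting noise, with a chi-square per gene of 2.51 to 9.84, and none held identical values. The first principal component held 65.1% of the variance and parted the treatments. The next held 19.5% and parted the cell populations. Levels are counts per M gene reads (CPM), given as the mean ± SD with n = 3 libraries per group.

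The knocked-down gene was measured first. Cebpg (ENSMUSG00000056216, chromosome 7, 35046422 to 35056573 in GRCm38) encodes C/EBP gamma, a basic leucine zipper protein that pairs with relatives such as ATF4. Its level was 51.8, 51.5 and 60.6 CPM in the control DMSO libraries and 4.63, 3.75 and 5.18 CPM in the knockdown DMSO libraries. With thapsigargin it was 211.4, 219.3 and 216.4 CPM in control libraries and 6.12, 5.58 and 5.29 CPM in knockdown libraries. Knockdown cells held 8.3% of the control mean in DMSO (log2 change -3.6, SE 0.08, adjusted p = 8.48e-25). Under thapsigargin they held 2.6% (-5.25, SE 0.08, adjusted p = 2.23e-30). Thapsigargin raised Cebpg in control cells (1.98, SE 0.06, adjusted p = 2.21e-23). In knockdown cells the change was smaller (0.33, SE 0.11, adjusted p = 0.0108). That call was lost without knockdown DMSO replicate 2 (0.2, adjusted p = 0.122) or knockdown thapsigargin replicate 1 (0.26, adjusted p = 0.0676). Over its 23 alternatives the adjusted p ran from 0.00122 to 0.122.

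**Figure D1:**
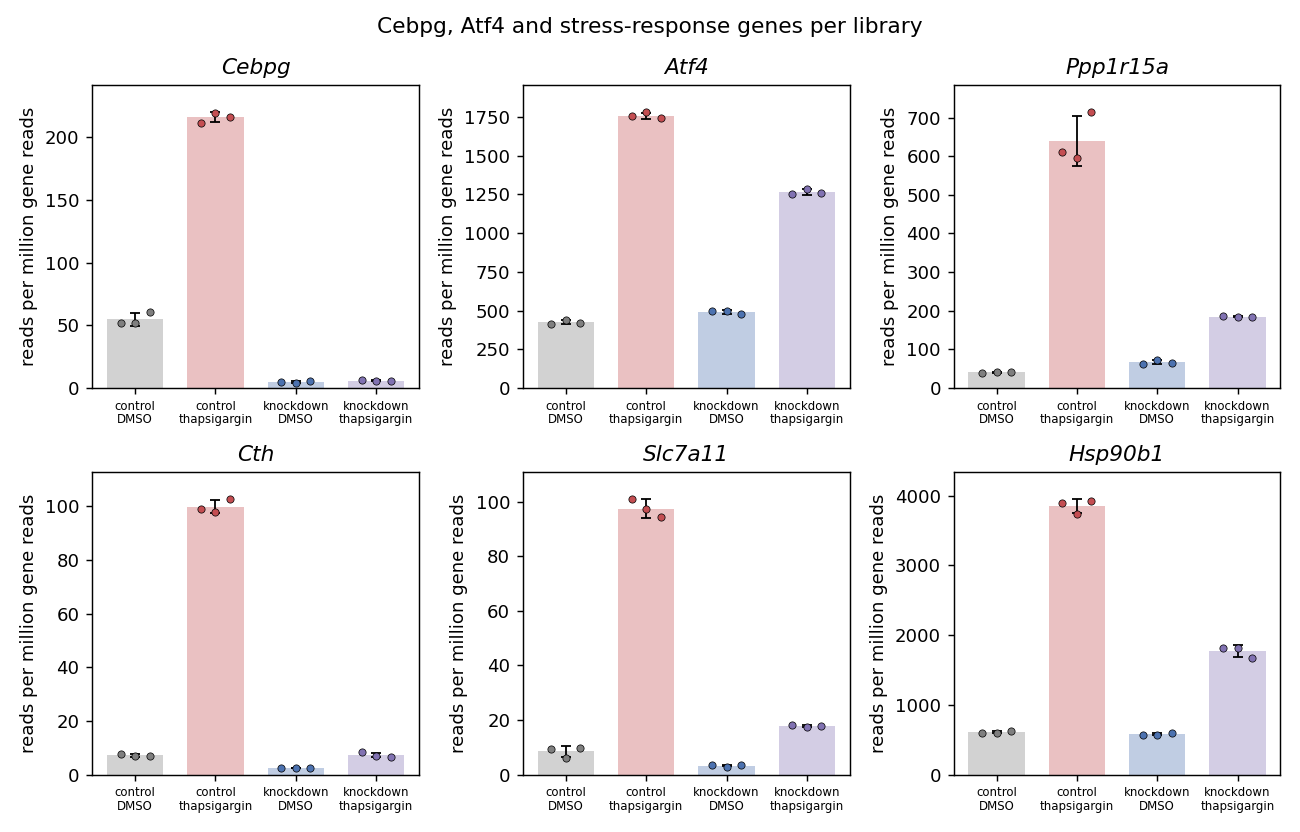
Level in CPM (y axis of each panel) of Cebpg, Atf4, Ppp1r15a, Cth, Slc7a11 and Hsp90b1 in the 4 groups; bars are means, error bars the SD, and points the 3 libraries of each group. All 6 genes were highest in the control thapsigargin libraries.

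Which transcripts differ with the knockdown in unstressed myoblasts was asked by comparing knockdown with control cells in DMSO. Hp, which encodes the acute phase protein haptoglobin, fell from 51.9 ± 3.18 to 0.705 ± 0.372 CPM (-6.21, SE 0.14). The acute phase gene Saa3 fell from 45.1 ± 1.97 to 2.7 ± 0.365 CPM. Camp, an antimicrobial peptide gene, fell from 10.1 ± 1.17 to 0.687 ± 0.0937 CPM, and Nxf7 fell from 10.5 ± 1.42 to 0.681 ± 0.217 CPM. Mgp, whose product inhibits calcification, fell from 207 ± 26.9 to 17.1 ± 2.75 CPM. Lce1g, a cornified envelope gene on chromosome 3, rose from 1.36 ± 0.381 to 39.3 ± 5.85 CPM (4.85, SE 0.2), and Prr9 rose from 5.86 ± 0.635 to 68.4 ± 2.49 CPM. Skeletal muscle actin, Acta1, rose from 7.17 ± 1.1 to 85.7 ± 16.1 CPM, and the matricellular gene Tinagl1 rose from 2.66 ± 0.0948 to 32.8 ± 2.34 CPM. Serpinb9e rose from 0.924 ± 0.197 to 13.6 ± 1.44 CPM and Prl2c2 rose from 37.4 ± 0.899 to 395 ± 15.2 CPM. Both have near-identical neighbours on chromosome 13, so the assignment of their reads is uncertain. Lce1g lies in a run of 9 genes, consecutive among the protein-coding genes tested, that each rose by at least 1 in log2. The run spans 92432582 to 93449077 on chromosome 3, and genes not tested can lie within it. Others of its family are in that run, so the assignment of its reads is uncertain too. In all, 8154 of 15828 genes tested changed (51.5%), 3955 up and 4199 down. Of these, 800 rose and 610 fell by at least 1 in log2.

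Of 15 genes of amino acid synthesis and one-carbon metabolism 2 rose, 12 fell and 1 did not pass, or 2 and 13 adjusted over the list alone, with a median of -0.63. Camera on amino acid synthesis gave an adjusted p = 2.3e-08, but adjusted p = 0.099 with an estimated correlation. Cth, which makes cysteine, fell from 7.14 ± 0.629 to 2.42 ± 0.112 CPM. Aldh1l2, a mitochondrial folate enzyme, fell from 105 ± 20.7 to 42.1 ± 2.46 CPM, and Pycr1, of proline synthesis, fell from 18.6 ± 1.04 to 9.16 ± 0.0864 CPM. Bcat1 did not pass (adjusted p = 0.0539). Cbs, which makes cystathionine, rose from 0.289 ± 0.1 to 0.617 ± 0.0827 CPM (1.08, SE 0.38, adjusted p = 0.0189). The Cbs call was lost without control DMSO replicate 1 (adjusted p = 0.0741), control DMSO replicate 2 (0.0714) or knockdown DMSO replicate 1 (0.0685), in a range of 0.0121 to 0.0741 over 22 alternatives. Of 22 ATF4 and CHOP stress regulators 7 rose, 8 fell and 7 did not pass, or 7 and 8 adjusted over the list alone, with a median of -0.07. Camera on ATF4 and CHOP regulators gave an adjusted p = 0.818. Atf4 itself rose from 424 ± 11.7 to 490 ± 10.5 CPM (0.21, SE 0.04, adjusted p = 5.97e-05), and Atf3, a stress-induced repressor, rose from 4.71 ± 0.0668 to 10.7 ± 1.02 CPM. Atf5 fell from 188 ± 8.47 to 76.3 ± 5.5 CPM, the pseudokinase gene Trib3 fell from 12.7 ± 1.81 to 6.18 ± 1.15 CPM and Ndrg1 fell from 64.8 ± 1.39 to 32.3 ± 1.13 CPM. Fgf21 and Vldlr did not pass (adjusted p = 0.136 and 0.303). In the C/EBP and ATF family, which holds Cebpg itself, 3 rose, 10 fell and 7 did not pass, or 4 and 10 adjusted over the list alone, with a median of -0.21. Camera on the C/EBP family gave an adjusted p = 1.73e-07. Without Cebpg in the list it was 0.000289, but the call was lost at 0.0595 with an estimated correlation as well, in a range of 3.1e-08 to 0.0595 over 24 alternatives. Cebpa, a differentiation factor, fell from 25.2 ± 0.659 to 4.12 ± 0.668 CPM and Cebpd fell from 50.5 ± 3.15 to 20.8 ± 1.76 CPM. Batf and Batf3 did not pass (adjusted p = 0.516 and 0.736).

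Among 17 p53 targets 14 rose, 2 fell and 1 did not pass, or 14 and 2 adjusted over the list alone, with a median of 0.52. Camera on p53 targets gave an adjusted p = 1.22e-09. Pmaip1, which encodes the pro-apoptotic protein NOXA, rose from 11.5 ± 1.17 to 27.1 ± 1.24 CPM. Mdm2, whose product marks p53 for degradation, rose from 156 ± 6.72 to 326 ± 8.99 CPM and Bax rose from 27.3 ± 1.33 to 47 ± 5.1 CPM. Fas did not pass (adjusted p = 0.106). Among 14 glutathione and NRF2 genes 11 rose, 1 fell and 2 did not pass, or 11 and 1 adjusted over the list alone, with a median of 0.39. Camera on the NRF2 list gave an adjusted p = 1.54e-07, but adjusted p = 0.0595 with an estimated correlation. Hmox1, which degrades haem, rose from 53.2 ± 0.359 to 141 ± 10.4 CPM and Nqo1 rose from 47 ± 1.73 to 82.3 ± 4.69 CPM. Prdx1 and Gsta4 did not pass (adjusted p = 0.0887 and 0.996). Among 12 cytosolic heat shock genes 11 rose, 0 fell and 1 did not pass, or 11 and 0 adjusted over the list alone, with a median of 0.36. Camera on heat shock genes gave an adjusted p = 5.19e-06, but adjusted p = 0.127 with an estimated correlation. The chaperone gene Hsph1 rose from 258 ± 17.6 to 393 ± 15.4 CPM and Hsp90aa1 rose from 1253 ± 35.1 to 1807 ± 26.5 CPM. Among 17 immediate early genes 12 rose, 4 fell and 1 did not pass, or 12 and 4 adjusted over the list alone, with a median of 0.46. Camera on immediate early genes gave an adjusted p = 3.66e-05, but adjusted p = 0.15 with an estimated correlation. Fosb rose from 2.82 ± 0.515 to 19.3 ± 3.57 CPM and Nr4a1 rose from 9.45 ± 0.644 to 25.1 ± 3.39 CPM, while Egr2 fell from 2.84 ± 0.176 to 1.25 ± 0.168 CPM.

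Of 16 myogenic regulators 2 rose, 8 fell and 6 did not pass, or 2 and 8 adjusted over the list alone, with a median of -0.23. Camera on myogenic regulators gave an adjusted p = 0.00357, but adjusted p = 0.143 with an estimated correlation. Myog, which starts terminal muscle differentiation, fell from 4.37 ± 1.19 to 0.662 ± 0.222 CPM. Pax7, a satellite cell marker, fell from 1.53 ± 0.0664 to 0.74 ± 0.149 CPM. Pax3 and Id1 did not pass (adjusted p = 0.337 and 0.107). Of 16 muscle differentiation genes 4 rose, 7 fell and 5 did not pass, or 4 and 8 adjusted over the list alone, with a median of -0.5. Camera on muscle genes gave an adjusted p = 0.818. Slow troponin, Tnnt1, fell from 5.01 ± 0.73 to 0.667 ± 0.146 CPM and embryonic myosin, Myh3, fell from 1.05 ± 0.367 to 0.347 ± 0.149 CPM, against the rise of Acta1. Of 21 extracellular matrix genes 6 rose, 12 fell and 3 did not pass, or 6 and 12 adjusted over the list alone, with a median of -0.39. Camera on matrix genes gave an adjusted p = 0.0318, but adjusted p = 0.499 with an estimated correlation. Col6a1 fell from 649 ± 8.64 to 198 ± 28.5 CPM and Postn fell from 70.3 ± 7.61 to 25.3 ± 4.89 CPM, while basement membrane collagen, Col4a1, rose from 388 ± 12.2 to 856 ± 35.9 CPM. The matrix call was also lost with the stricter filter (adjusted p = 0.0603), with only the compared groups (0.0537) and without control thapsigargin replicate 3 (0.0733), in a range of 0.000697 to 0.499 over 22 alternatives. Of 18 G2 and mitosis genes 13 rose, 0 fell and 5 did not pass, or 14 and 0 adjusted over the list alone, with a median of 0.25. Camera on mitosis genes gave an adjusted p = 0.00029, but adjusted p = 0.172 with an estimated correlation. Ccnb1 rose from 130 ± 4.5 to 185 ± 7.38 CPM, and Kif11 did not pass (adjusted p = 0.105). Of 8 epithelial markers 4 rose, 0 fell and 4 did not pass, or 4 and 0 adjusted over the list alone, with a median of 1.04. Camera on epithelial markers gave an adjusted p = 0.124.

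Thapsigargin in control cells shows the ER stress response with Cebpg in place. Car6, a secreted carbonic anhydrase, rose from 0.453 ± 0.0338 to 131 ± 6 CPM (8.17, SE 0.11, adjusted p = 1.78e-33). Grhl2, an epithelial transcription factor, rose from 0.0385 ± 0.0442 to 8.54 ± 1.5 CPM. H2-M10.1, a class Ib histocompatibility gene, had 0 reads in the control DMSO group and 13 ± 0.812 CPM with thapsigargin. That is at least 449-fold more against a floor of 3 reads over the group, a floor that covers counting error only. Cyp3a57, Gabrr1 and Icam1 each had 2 reads over the control DMSO group. They reached 7.8 ± 1.18, 6.51 ± 1.12 and 5.14 ± 0.684 CPM. H2-M10.1 and Cyp3a57 have close paralogs, so their identity is uncertain. Oaf fell from 111 ± 8.02 to 8.25 ± 0.561 CPM (-3.75, SE 0.07), Xkr5 fell from 5.63 ± 0.463 to 0.413 ± 0.133 CPM and the sulphotransferase gene Chst15 fell from 30.1 ± 0.841 to 2.57 ± 0.341 CPM. The integrin gene Itga3 fell from 145 ± 8.72 to 13.8 ± 0.782 CPM, Pxylp1 fell from 74.3 ± 3.69 to 7.2 ± 0.57 CPM and the collagen cross-linking gene Pxdn fell from 182 ± 5.72 to 17.9 ± 0.266 CPM. In all, 11828 genes changed (74.7%), 5970 up and 5858 down. Of these, 2556 rose and 1613 fell by at least 1 in log2.

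Of 16 ER chaperone genes 15 rose, 1 fell and 0 did not pass, or 15 and 1 adjusted over the list alone, with a median of 2.17. Camera on ER chaperones gave an adjusted p = 1.33e-45. Hspa5, which encodes the main ER chaperone BiP, rose from 1698 ± 56.6 to 20738 ± 322 CPM (3.61, SE 0.05). Sdf2l1 rose from 39.1 ± 2.5 to 441 ± 10 CPM and Creld2 rose from 112 ± 1.43 to 1034 ± 15.2 CPM. Of 22 genes of ER-associated degradation and the secretory pathway 22 rose, 0 fell and 0 did not pass, or 22 and 0 adjusted over the list alone, with a median of 1.24. Camera on the degradation and secretory list gave an adjusted p = 1.32e-26. Herpud1, of the degradation complex, rose from 73.1 ± 3.66 to 2136 ± 47.8 CPM (4.87, SE 0.05), and Sel1l rose from 158 ± 6.31 to 970 ± 10.8 CPM. Of 22 ATF4 and CHOP stress regulators 20 rose, 1 fell and 1 did not pass, or 20 and 1 adjusted over the list alone, with a median of 2.34. Camera on ATF4 and CHOP regulators gave an adjusted p = 2.91e-47. Fgf21, a stress hormone gene, rose from 0.163 ± 0.0587 to 30.6 ± 2.15 CPM. Atf3 rose from 4.71 ± 0.0668 to 227 ± 4.4 CPM, Trib3 rose from 12.7 ± 1.81 to 391 ± 5.5 CPM and Ddit3, which encodes CHOP, rose from 16.8 ± 0.516 to 406 ± 6.47 CPM. Atf4 rose from 424 ± 11.7 to 1759 ± 18.6 CPM (2.05, SE 0.04), and the death receptor gene Tnfrsf10b did not pass (adjusted p = 0.299). In the C/EBP and ATF family 16 rose, 1 fell and 3 did not pass, or 16 and 1 adjusted over the list alone, with a median of 0.9. Camera on the C/EBP family gave an adjusted p = 9.05e-13. Creb3l1 and Atf6b did not pass (adjusted p = 0.205 and 0.729).

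Among 15 genes of amino acid synthesis 14 rose, 0 fell and 1 did not pass, or 14 and 0 adjusted over the list alone, with a median of 1.8. Camera on amino acid synthesis gave an adjusted p = 4.37e-25. Cth rose from 7.14 ± 0.629 to 99.8 ± 2.5 CPM, Gpt2 rose from 58.1 ± 4.97 to 388 ± 10.6 CPM and Psph, the last enzyme of serine synthesis, rose from 50.6 ± 2.85 to 231 ± 2.92 CPM. Cbs did not pass (adjusted p = 0.127). Among 13 amino acid transporters 11 rose, 1 fell and 1 did not pass, or 11 and 1 adjusted over the list alone, with a median of 1.24. Camera on transporters gave an adjusted p = 3.25e-15. Slc7a11, the cystine importer, rose by 3.52 in log2 and its partner Slc3a2 rose from 226 ± 11.2 to 2066 ± 69.7 CPM. Slc43a1 did not pass (adjusted p = 0.302). Among 21 genes of the aminoacyl-tRNA synthetase list, which also holds the tRNA exportin gene Xpot, 19 rose, 0 fell and 2 did not pass, or 19 and 0 adjusted over the list alone, with a median of 1.34. Camera on the synthetase list gave an adjusted p = 4.76e-17. Wars rose from 121 ± 5.15 to 567 ± 13.7 CPM and Gars rose from 355 ± 17.2 to 1092 ± 7.33 CPM. Mars and Qars did not pass (adjusted p = 0.0714 and 0.0789). Among 22 interferon response genes 18 rose, 2 fell and 2 did not pass, or 18 and 2 adjusted over the list alone, with a median of 1.4. Camera on interferon genes gave an adjusted p = 0.00695, but adjusted p = 0.358 with an estimated correlation. The antiviral gene Mx2 rose from 0.241 ± 0.104 to 7.24 ± 1.26 CPM and Ifi44 rose from 0.856 ± 0.242 to 8.41 ± 0.901 CPM. Among 8 epithelial markers 7 rose, 1 fell and 0 did not pass, or 7 and 1 adjusted over the list alone, with a median of 2.53. Camera on epithelial markers gave an adjusted p = 0.0926. Among 6 endothelial markers 4 rose, 0 fell and 2 did not pass, or 4 and 0 adjusted over the list alone, with a median of 2.6. Camera on endothelial markers gave an adjusted p = 0.0768. Vwf, the von Willebrand factor gene, rose from 0.28 ± 0.0625 to 4.35 ± 0.678 CPM.

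Growth and matrix groups were also tested with thapsigargin in control cells. Of 18 S phase and replication genes 0 rose, 17 fell and 1 did not pass, or 0 and 17 adjusted over the list alone, with a median of -1.12. Camera on S phase genes gave an adjusted p = 1.31e-12, but adjusted p = 0.0612 with an estimated correlation. Cyclin E1, Ccne1, fell from 51.1 ± 1.71 to 6.69 ± 0.649 CPM and the replicative helicase gene Mcm6 fell from 264 ± 2.15 to 98.5 ± 4.75 CPM. Cdt1 did not pass (adjusted p = 0.262). Of 18 G2 and mitosis genes 0 rose, 15 fell and 3 did not pass, or 0 and 15 adjusted over the list alone, with a median of -0.57. Camera on mitosis genes gave an adjusted p = 0.000318, but adjusted p = 0.172 with an estimated correlation. Cdk1, the mitotic kinase, fell from 198 ± 1.7 to 86.8 ± 0.801 CPM, while Cdc20 did not pass (adjusted p = 0.205). Of 21 extracellular matrix genes 1 rose, 19 fell and 1 did not pass, or 1 and 19 adjusted over the list alone, with a median of -0.66. Camera on matrix genes gave an adjusted p = 9.15e-07, but adjusted p = 0.137 with an estimated correlation. Thbs1 fell from 619 ± 13.7 to 79 ± 1.32 CPM and Col3a1 fell from 4238 ± 64.2 to 1249 ± 84.4 CPM, while Col5a2 did not pass (adjusted p = 0.491). Of 20 cholesterol synthesis genes 3 rose, 16 fell and 1 did not pass, or 3 and 16 adjusted over the list alone, with a median of -0.54. Camera on cholesterol synthesis gave an adjusted p = 0.000705, but adjusted p = 0.143 with an estimated correlation. Dhcr7, the last enzyme of the pathway, fell from 33.8 ± 1.25 to 6.61 ± 0.738 CPM, and Fdps did not pass (adjusted p = 0.936). Of 12 cytosolic heat shock genes 2 rose, 8 fell and 2 did not pass, or 2 and 8 adjusted over the list alone, with a median of -0.83. Camera on heat shock genes gave an adjusted p = 0.00116, but adjusted p = 0.242 with an estimated correlation. Hspa1b fell from 51.5 ± 1.26 to 11.9 ± 1.07 CPM and Hspb1 fell from 341 ± 8.72 to 129 ± 2.14 CPM. Of 16 myogenic regulators 4 rose, 9 fell and 3 did not pass, or 4 and 9 adjusted over the list alone, with a median of -0.44. Camera on myogenic regulators gave an adjusted p = 0.221. Myf5 rose from 61.8 ± 6.18 to 252 ± 7.15 CPM and Pax7 fell from 1.53 ± 0.0664 to 0.235 ± 0.0369 CPM.

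Knockdown cells were then compared with and without thapsigargin to see the response with most Cebpg mRNA lost. Cyp3a57, Gabrr1 and Npffr1, with 1, 2 and 3 reads over the knockdown DMSO group, reached 13.2 ± 1.17, 9.6 ± 1.01 and 5.11 ± 0.579 CPM. Pnma5 rose from 0.0613 ± 0.0533 to 7.96 ± 0.28 CPM (6.96, SE 0.28, adjusted p = 1.36e-20), Grhl2 rose from 0.0889 ± 0.0576 to 7.42 ± 0.0657 CPM and Rab15 rose from 0.291 ± 0.081 to 12.4 ± 1.01 CPM. The basement membrane gene Nid1 fell from 903 ± 39.9 to 74.9 ± 6.22 CPM (-3.59, SE 0.06, adjusted p = 2.61e-30). Oaf fell from 100 ± 2.27 to 9.09 ± 0.859 CPM, Islr fell from 12.3 ± 2.63 to 1.16 ± 0.543 CPM and Pxdn fell from 166 ± 8.41 to 17.9 ± 0.239 CPM. Pbxip1 fell from 157 ± 1.19 to 21.7 ± 0.693 CPM and the activity-regulated gene Npas4 fell from 5.47 ± 0.18 to 0.761 ± 0.232 CPM. In all, 11051 genes changed (69.8%), 5611 up and 5440 down. Of these, 2085 rose and 1011 fell by at least 1 in log2. With scaling on library size alone 60.5% of calls were higher, against 50.8%.

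Of 16 ER chaperone genes in knockdown cells 15 rose, 1 fell and 0 did not pass, or 15 and 1 adjusted over the list alone, with a median of 1.27. Camera on ER chaperones gave an adjusted p = 1e-34. Hspa5 rose from 1298 ± 21.6 to 10749 ± 313 CPM and Manf rose from 93.6 ± 3.94 to 441 ± 23.2 CPM. Of 22 ER-associated degradation and secretory pathway genes 20 rose, 0 fell and 2 did not pass, or 20 and 0 adjusted over the list alone, with a median of 0.75. Camera on the degradation and secretory list gave an adjusted p = 6.14e-20. Herpud1 rose from 75.8 ± 4.05 to 914 ± 7.75 CPM, while Os9 did not pass (adjusted p = 0.676). Of 22 ATF4 and CHOP stress regulators 20 rose, 2 fell and 0 did not pass, or 20 and 2 adjusted over the list alone, with a median of 1.69. Camera on ATF4 and CHOP regulators gave an adjusted p = 1.64e-34. Fgf21 rose from 0.0579 ± 0.1 to 4.94 ± 0.861 CPM, Trib3 rose from 6.18 ± 1.15 to 167 ± 6.56 CPM and Ddit3 rose from 18 ± 1.23 to 193 ± 10.5 CPM. Atf4 rose from 490 ± 10.5 to 1266 ± 18.3 CPM (1.37, SE 0.04). Of 15 amino acid synthesis genes 13 rose, 0 fell and 2 did not pass, or 13 and 0 adjusted over the list alone, with a median of 1.05. Camera on amino acid synthesis gave an adjusted p = 1.31e-10, but adjusted p = 0.0628 with an estimated correlation. Gpt2 rose from 31.3 ± 0.895 to 148 ± 4.97 CPM and Cth rose from 2.42 ± 0.112 to 7.35 ± 0.8 CPM, while Mthfd1l did not pass (adjusted p = 0.994). Of 13 transporters 8 rose, 1 fell and 4 did not pass, or 8 and 1 adjusted over the list alone, with a median of 0.98. Camera on transporters gave an adjusted p = 5.3e-07, but adjusted p = 0.0595 with an estimated correlation. Slc3a2 rose from 228 ± 10.1 to 1078 ± 4.05 CPM, while Slc36a4 did not pass (adjusted p = 0.13). Of 21 genes of the synthetase list, Xpot included, 17 rose, 2 fell and 2 did not pass, or 17 and 2 adjusted over the list alone, with a median of 0.67. Camera on the synthetase list gave an adjusted p = 5.67e-10, but adjusted p = 0.0876 with an estimated correlation. Aars rose from 383 ± 22.3 to 1009 ± 20.8 CPM, while Hars and Vars did not pass (adjusted p = 0.322 and 0.756). In the C/EBP and ATF family 16 rose, 1 fell and 3 did not pass, or 17 and 1 adjusted over the list alone, with a median of 0.63. Camera on the C/EBP family gave an adjusted p = 1.52e-12.

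Among 20 cholesterol synthesis genes in knockdown cells 1 rose, 18 fell and 1 did not pass, or 1 and 18 adjusted over the list alone, with a median of -0.83. Camera on cholesterol synthesis gave an adjusted p = 4.51e-13. Dhcr7 fell from 26.7 ± 0.685 to 6.46 ± 0.648 CPM and Nsdhl fell from 68.2 ± 3.47 to 24.7 ± 0.848 CPM, while Mvd did not pass (adjusted p = 0.0734). Among 21 matrix genes 0 rose, 20 fell and 1 did not pass, or 0 and 20 adjusted over the list alone, with a median of -0.97. Camera on matrix genes gave an adjusted p = 8.63e-13, but adjusted p = 0.0523 with an estimated correlation. Col6a1 fell from 198 ± 28.5 to 40.6 ± 8.5 CPM and Thbs1 fell from 1050 ± 38.3 to 313 ± 41 CPM, while Postn did not pass (adjusted p = 0.773). Among 18 S phase genes 1 rose, 16 fell and 1 did not pass, or 1 and 16 adjusted over the list alone, with a median of -0.64. Camera on S phase genes gave an adjusted p = 7.27e-09, but adjusted p = 0.112 with an estimated correlation. Ccne1 fell from 63.4 ± 1.86 to 15.9 ± 0.562 CPM and Rrm2, a ribonucleotide reductase gene, fell from 932 ± 18 to 396 ± 25.9 CPM. Among 19 glycolysis and hypoxia genes 2 rose, 17 fell and 0 did not pass, or 2 and 17 adjusted over the list alone, with a median of -0.61. Camera on glycolysis genes gave an adjusted p = 1.02e-05, but adjusted p = 0.0876 with an estimated correlation. The glucose transporter gene Slc2a1 fell from 129 ± 4.23 to 50.6 ± 0.164 CPM and Pgam1 fell from 406 ± 9.64 to 189 ± 9.13 CPM. Among 10 mRNAs of mitochondrial DNA 0 rose, 8 fell and 2 did not pass, or 0 and 8 adjusted over the list alone, with a median of -0.72. Camera on mitochondrial mRNAs gave an adjusted p = 0.00151, but adjusted p = 0.271 with an estimated correlation. The complex I gene mt-Nd1 fell from 3817 ± 261 to 2060 ± 202 CPM, while mt-Co3 did not pass (adjusted p = 0.226). Among 8 epithelial markers 5 rose, 0 fell and 3 did not pass, or 5 and 0 adjusted over the list alone, with a median of 2.11. Camera on epithelial markers gave an adjusted p = 0.0124, but adjusted p = 0.0851 with an estimated correlation. Keratin 18, Krt18, rose from 0.0908 ± 0.00551 to 3.93 ± 0.628 CPM.

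**Figure D2:**
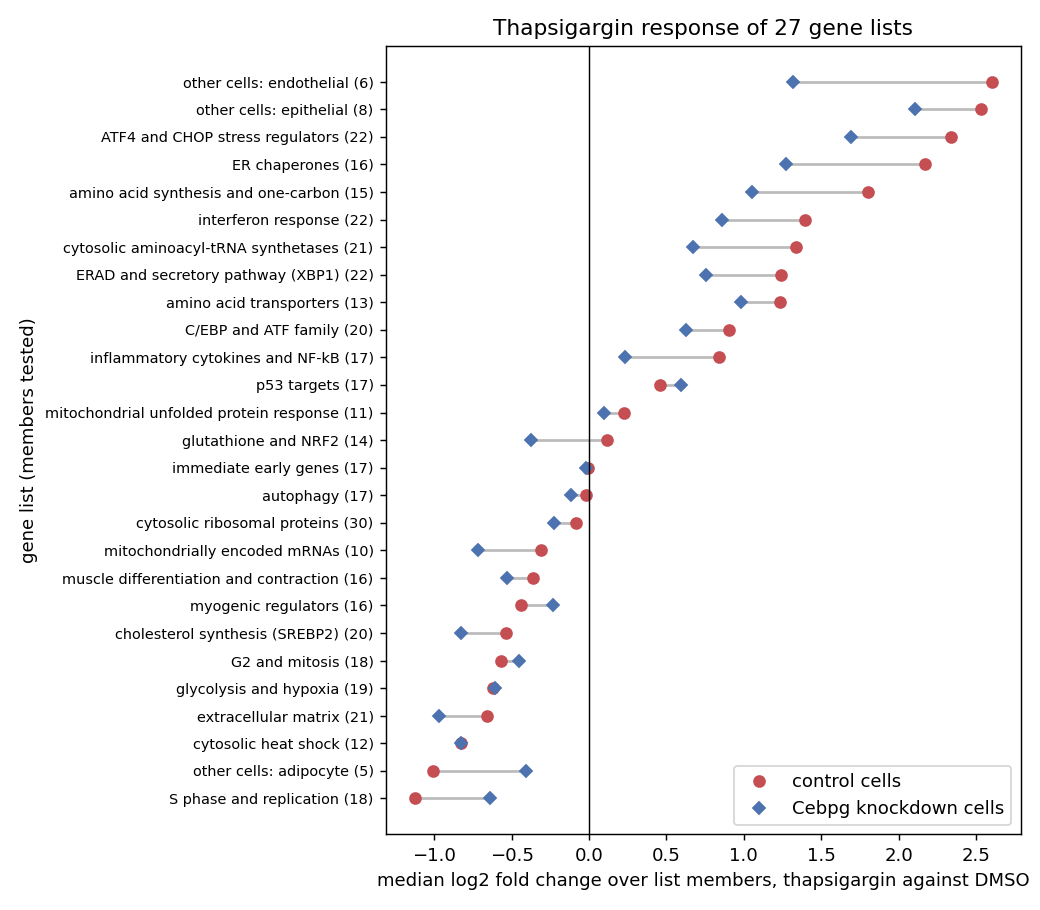
Median log2 change with thapsigargin (x axis) of the tested members of 27 gene lists (y axis), with circles for control cells and diamonds for knockdown cells. The medians of the stress and amino acid lists lay further from 0 in control cells.

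Which stress transcripts differed with the knockdown was asked by comparing both cell populations under thapsigargin. Values of knockdown cells are given first. Car6 was at 0.783 ± 0.24 against 131 ± 6 CPM (-7.37, SE 0.11, adjusted p = 2.69e-32) and Hp at 0.339 ± 0.129 against 18.1 ± 0.751 CPM (-5.7, SE 0.18). Avil, which encodes an actin-severing protein, was at 1.85 ± 0.446 against 67.5 ± 7.63 CPM, and Pi16 at 0.284 ± 0.151 against 8.98 ± 0.517 CPM. Dnmt3l, a cofactor of DNA methylation, was at 0.169 ± 0.091 against 6.27 ± 0.749 CPM. Among higher genes, Lce1g was at 32.9 ± 3.99 against 1.51 ± 0.538 CPM (4.47, SE 0.19) and Acta1 at 46.5 ± 6.33 against 5 ± 0.299 CPM. The cadherin gene Fat4 was at 10.7 ± 0.36 against 1.87 ± 0.356 CPM, and Serpinb9e at 16.2 ± 1.79 against 2.32 ± 0.114 CPM. Prl2c2 was at 207 ± 24.1 against 24.3 ± 2.17 CPM and Prl2c3 at 41.6 ± 3.61 against 4.25 ± 0.423 CPM, with the same doubt about near-identical neighbours. In all, 9010 genes changed (56.9%), 4515 higher and 4495 lower. Of these, 804 were higher and 943 lower by at least 1 in log2. With scaling on library size alone 66.6% of calls were higher, against 50.1%.

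Of 15 amino acid synthesis genes under thapsigargin 0 were higher, 14 lower and 1 did not pass, or 0 and 14 adjusted over the list alone, with a median of -1.36. Camera on amino acid synthesis gave an adjusted p = 9.01e-38. Cth was at 7.35 ± 0.8 against 99.8 ± 2.5 CPM (-3.76, SE 0.07), Aldh1l2 at 183 ± 17.6 against 815 ± 18.9 CPM and Psat1, of serine synthesis, at 286 ± 8.74 against 824 ± 8.55 CPM. Of 13 transporters 0 were higher, 12 lower and 1 did not pass, or 0 and 13 adjusted over the list alone, with a median of -1.01. Camera on transporters gave an adjusted p = 4.49e-18. The glutamine carrier gene Slc1a5 was at 18.9 ± 0.907 against 59.7 ± 2.32 CPM, Slc6a9 at 26 ± 2.35 against 116 ± 6.44 CPM and Slc7a5 at 507 ± 13.2 against 1400 ± 54 CPM. Of 21 genes of the synthetase list, Xpot included, 2 were higher, 16 lower and 3 did not pass, or 2 and 16 adjusted over the list alone, with a median of -0.42. Camera on the synthetase list gave an adjusted p = 1.69e-08, but adjusted p = 0.119 with an estimated correlation. Eprs was at 440 ± 17.7 against 956 ± 16.6 CPM, while Qars and Dars did not pass (adjusted p = 0.179 and 0.153). Of 22 ATF4 and CHOP regulators 2 were higher, 20 lower and 0 did not pass, or 2 and 20 adjusted over the list alone, with a median of -0.8. Camera on ATF4 and CHOP regulators gave an adjusted p = 1.05e-18. The ER oxidase gene Ero1l was at 134 ± 3.45 against 653 ± 19.9 CPM, Ddit4 at 78.4 ± 7.32 against 274 ± 14.5 CPM and Fgf21 at 4.94 ± 0.861 against 30.6 ± 2.15 CPM. Ppp1r15a, which encodes the phosphatase subunit GADD34, was at 185 ± 1.55 against 639 ± 64.7 CPM. Atf4 itself was at 1266 ± 18.3 against 1759 ± 18.6 CPM (-0.48, SE 0.04, adjusted p = 4.37e-12). In the C/EBP and ATF family, which holds Cebpg, 1 were higher, 16 lower and 3 did not pass, or 1 and 16 adjusted over the list alone, with a median of -0.56. Camera on the C/EBP family gave an adjusted p = 7.91e-12. Without Cebpg in the list it was 6.04e-07, and 0.0201 with an estimated correlation, in a range of 5.26e-13 to 0.0201 over 24 alternatives. Atf6, an ER stress sensor, was at 185 ± 7.66 against 485 ± 8.7 CPM, and Ddit3 at 193 ± 10.5 against 406 ± 6.47 CPM.

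Among 16 ER chaperone genes under thapsigargin 0 were higher, 16 lower and 0 did not pass, or 0 and 16 adjusted over the list alone, with a median of -0.73. Camera on ER chaperones gave an adjusted p = 1.04e-18. Pdia4, a disulphide isomerase gene, was at 729 ± 9.57 against 1884 ± 26.1 CPM, and Hsp90b1, which encodes GRP94, at 1768 ± 85.9 against 3851 ± 96 CPM. Among 22 ER-associated degradation and secretory pathway genes 0 were higher, 20 lower and 2 did not pass, or 0 and 20 adjusted over the list alone, with a median of -0.49. Camera on the degradation and secretory list gave an adjusted p = 1.11e-15. Sel1l was at 267 ± 10.1 against 970 ± 10.8 CPM and Herpud1 at 914 ± 7.75 against 2136 ± 47.8 CPM, while Derl3 and Ufd1 did not pass (adjusted p = 0.762 and 0.765). Among 20 cholesterol synthesis genes 3 were higher, 16 lower and 1 did not pass, or 3 and 16 adjusted over the list alone, with a median of -0.65. Camera on cholesterol synthesis gave an adjusted p = 2.84e-09. Hmgcs1 was at 34.3 ± 0.991 against 85 ± 2.35 CPM and Fdps at 1.22 ± 0.184 against 5.04 ± 0.402 CPM, while Dhcr7 did not pass (adjusted p = 0.89). Among 22 interferon response genes 1 were higher, 16 lower and 5 did not pass, or 1 and 17 adjusted over the list alone, with a median of -0.87. Camera on interferon genes gave an adjusted p = 0.00075, but adjusted p = 0.23 with an estimated correlation. Ifi44 was at 0.673 ± 0.208 against 8.41 ± 0.901 CPM, while Oas1a and Ifit1 did not pass (adjusted p = 0.0873 and 0.0547). Among 18 S phase genes 14 were higher, 2 lower and 2 did not pass, or 14 and 2 adjusted over the list alone, with a median of 0.44. Camera on S phase genes gave an adjusted p = 1.32e-05, but adjusted p = 0.188 with an estimated correlation. Ccne1 was at 15.9 ± 0.562 against 6.69 ± 0.649 CPM and Rrm2 at 396 ± 25.9 against 219 ± 7.22 CPM, while Pcna did not pass (adjusted p = 0.878). Among 21 matrix genes 6 were higher, 15 lower and 0 did not pass, or 6 and 15 adjusted over the list alone, with a median of -0.6. Camera on matrix genes gave an adjusted p = 0.00425, but adjusted p = 0.364 with an estimated correlation. Col6a1 was at 40.6 ± 8.5 against 175 ± 15 CPM, while Thbs1 was higher at 313 ± 41 against 79 ± 1.32 CPM. Among 8 epithelial markers 6 were higher, 1 lower and 1 did not pass, or 6 and 1 adjusted over the list alone, with a median of 1.11. Camera on epithelial markers gave an adjusted p = 0.0926. Krt18 was at 3.93 ± 0.628 against 1.44 ± 0.103 CPM, while Esrp1, a splicing factor gene, was at 0.0598 ± 0.0279 against 0.617 ± 0.177 CPM.

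Whether the response to thapsigargin itself differed with the knockdown was tested as the difference of both log2 responses, knockdown minus control. Ppp1r15a went from 40.3 ± 1.43 to 639 ± 64.7 CPM in control cells and from 66.5 ± 5.27 to 185 ± 1.55 CPM in knockdown cells (-2.51, SE 0.08, adjusted p = 1.1e-18). Ero1l went from 77.6 ± 6.61 to 653 ± 19.9 CPM and from 74.3 ± 2.4 to 134 ± 3.45 CPM (-2.22, SE 0.07). Atf4 had a difference of -0.68 (adjusted p = 1.64e-11) and Cebpg one of -1.66 (adjusted p = 7.07e-12). Large negative differences were those of Avil (-4.88, SE 0.34), Car6 (-4.29, SE 0.99, adjusted p = 0.000826) and Als2cl (-4, SE 0.3). The cornified envelope gene Cdsn (-3.93, SE 0.16) and the lipocalin gene Lcn2 (-3.88, SE 0.41) were also negative. Icam1, with 2 reads over the control DMSO group, reached 5.14 ± 0.684 CPM in control and 2.19 ± 0.439 CPM in knockdown cells. The Car6 call was lost without knockdown DMSO replicate 2 (-3.63, adjusted p = 0.0574), in a range of 2.43e-08 to 0.0574 over 22 alternatives. Large positive differences were those of Lrrc15 (2.52, SE 0.33), Cebpa (2.2, SE 0.16) and Csf2rb (2.06, SE 0.16). The chemokine gene Cxcl12 (2.11, SE 0.08) went from 89.1 ± 5.88 to 13.9 ± 0.462 CPM in control cells and from 102 ± 0.826 to 68.8 ± 2.76 CPM in knockdown cells. Pxylp1 (2.04, SE 0.1) and Cxcr6 (1.87, SE 0.34) were also positive.

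The response of 5598 genes differed (35.4%), 2794 with a positive and 2804 with a negative difference. By at least 1 in log2, 305 were positive and 554 negative. With scaling on library size alone 75.6% of calls were positive, against 49.9%. Of the 2299 genes whose average response was a rise of at least 1, 553 (24.1%) had a negative and 115 (5%) a positive difference. Their median rise was 2.33 in control and 1.79 in knockdown cells, and their median difference -0.43. Of the 1222 genes whose average response was a fall of at least 1, 84 (6.9%) had a negative and 443 (36.3%) a positive difference. Their median response was -1.47 in control and -1.18 in knockdown cells, and their median difference 0.33. Across all genes tested the responses correlated with a Pearson r of 0.866 and a Spearman rho of 0.826. Genes are not independent replicates, so no p is given.

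**Figure D3:**
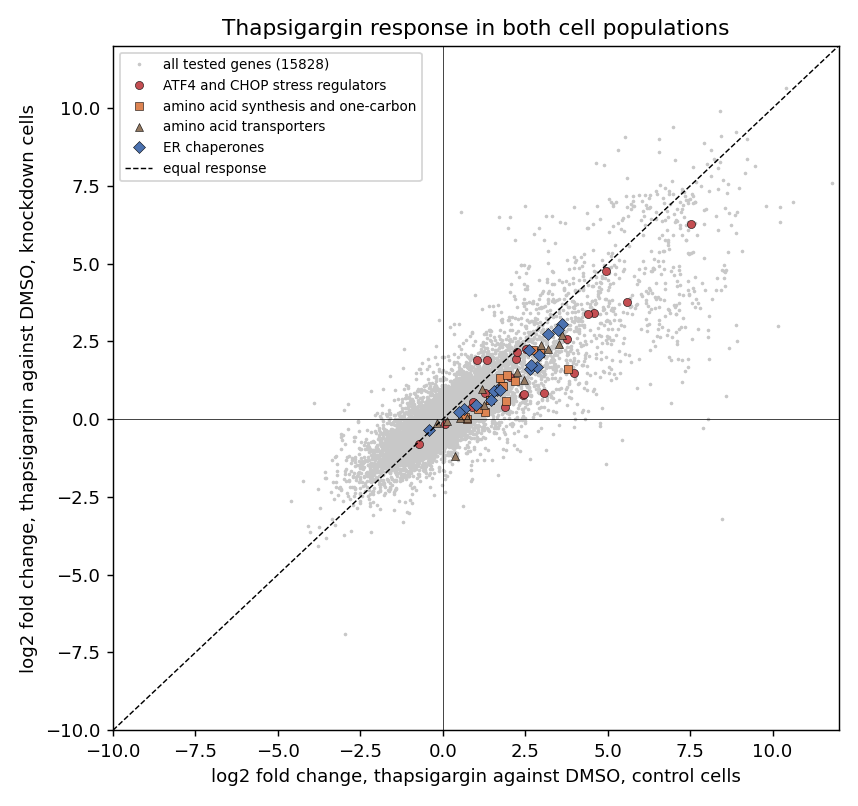
Log2 change with thapsigargin in control cells (x axis) and in knockdown cells (y axis) of 15828 genes, with members of 4 gene lists coloured and a dashed line where both responses are equal. Cth lay below that line, at 3.81 in control and 1.61 in knockdown cells.

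Among 22 ATF4 and CHOP regulators 2 had a positive difference, 16 a negative one and 4 did not pass, or 2 and 16 adjusted over the list alone, with a median of -0.59. Camera on ATF4 and CHOP regulators gave an adjusted p = 6.14e-20. Atf3 (-1.82, SE 0.09) and the stress sensor gene Sesn2 (-1.66, SE 0.08) were negative, while Fgf21 did not pass (adjusted p = 0.343). Among 15 amino acid synthesis genes 0 had a positive difference, 14 a negative one and 1 did not pass, or 0 and 14 adjusted over the list alone, with a median of -0.75. Camera on amino acid synthesis gave an adjusted p = 7.34e-21. Cth (-2.2), Got1 (-1.33), Phgdh, the entry enzyme of serine synthesis (-1.05), and Psph (-0.96) were negative. Among 13 transporters 0 had a positive difference, 10 a negative one and 3 did not pass, or 0 and 11 adjusted over the list alone, with a median of -0.74. Camera on transporters gave an adjusted p = 3.87e-13. Slc1a5 (-1.55), Slc7a1 (-1.21), Slc7a11 (-1.1) and Slc3a2 (-0.95) were negative. Among 21 genes of the synthetase list, Xpot included, 0 had a positive difference, 16 a negative one and 5 did not pass, or 1 and 16 adjusted over the list alone, with a median of -0.36. Camera on the synthetase list gave an adjusted p = 6.86e-12, but adjusted p = 0.0763 with an estimated correlation. Wars (-0.89), Gars (-0.88) and Eprs (-0.84) were negative. Among 16 ER chaperone genes 0 had a positive difference, 15 a negative one and 1 did not pass, or 0 and 15 adjusted over the list alone, with a median of -0.63. Camera on ER chaperones gave an adjusted p = 2.31e-21. Pdia4 (-1.17), Hsp90b1 (-1.05) and Dnajc3 (-0.92) were negative. Among 22 ER-associated degradation and secretory pathway genes 1 had a positive difference, 18 a negative one and 3 did not pass, or 1 and 19 adjusted over the list alone, with a median of -0.36. Camera on the degradation and secretory list gave an adjusted p = 1.44e-12. Sel1l (-1.46), Herpud1 (-1.28) and Syvn1 (-0.94) were negative.

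Of 14 glutathione and NRF2 genes 0 had a positive difference, 11 a negative one and 3 did not pass, or 0 and 11 adjusted over the list alone, with a median of -0.61. Camera on the NRF2 list gave an adjusted p = 2.49e-14. Hmox1 (-2, SE 0.07) and Gsta4 (-1.22, SE 0.1) were negative. The NRF2 list was not called for thapsigargin in control cells (median 0.114, camera adjusted p = 0.198) or for the knockdown in thapsigargin (-0.203, 0.0926). For thapsigargin in knockdown cells its median was -0.375 (camera adjusted p = 0.0105, but adjusted p = 0.276 with an estimated correlation). Of 20 cholesterol synthesis genes 2 had a positive difference, 13 a negative one and 5 did not pass, or 3 and 13 adjusted over the list alone, with a median of -0.44. Camera on cholesterol synthesis gave an adjusted p = 5.65e-07. Mvd (-1.08) was negative. Of 18 S phase genes 13 had a positive difference, 1 a negative one and 4 did not pass, or 13 and 1 adjusted over the list alone, with a median of 0.36. Camera on S phase genes gave an adjusted p = 7.08e-07, but adjusted p = 0.15 with an estimated correlation. Ccne1 (0.93) and Mcm6 (0.84) were positive. In the C/EBP and ATF family 3 had a positive difference, 10 a negative one and 7 did not pass, or 3 and 10 adjusted over the list alone, with a median of -0.28. Camera on the C/EBP family gave an adjusted p = 0.00504, but adjusted p = 0.099 with an estimated correlation. Without Cebpg in the list it was 0.0305, but 0.188 with an estimated correlation, in a range of 2.46e-05 to 0.188 over 23 alternatives. Of 11 mitochondrial unfolded protein response genes 1 had a positive difference, 6 a negative one and 4 did not pass, or 1 and 6 adjusted over the list alone, with a median of -0.29. Camera on the mitochondrial response gave an adjusted p = 0.000183, but adjusted p = 0.114 with an estimated correlation. Of 22 interferon response genes 0 had a positive difference, 7 a negative one and 15 did not pass, or 0 and 7 adjusted over the list alone, with a median of -0.51. Camera on interferon genes gave an adjusted p = 0.0305, but adjusted p = 0.463 with an estimated correlation. Of 10 mRNAs of mitochondrial DNA 0 had a positive difference, 7 a negative one and 3 did not pass, or 0 and 7 adjusted over the list alone, with a median of -0.39. Camera on mitochondrial mRNAs gave an adjusted p = 0.00744, but adjusted p = 0.363 with an estimated correlation. Of 19 glycolysis and hypoxia genes 2 had a positive difference, 4 a negative one and 13 did not pass, or 2 and 4 adjusted over the list alone, with a median of -0.07. Camera on glycolysis genes gave an adjusted p = 0.000192, but adjusted p = 0.119 with an estimated correlation. Of 8 epithelial markers 2 had a positive difference, 0 a negative one and 6 did not pass, or 2 and 0 adjusted over the list alone, with a median of -1.09. Camera pointed up for them against that median (adjusted p = 0.818).

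Over the 5 comparisons camera called 78 of 135 list tests, and 28 of those calls held with an estimated correlation. They were the C/EBP and p53 lists for the knockdown in DMSO, but the C/EBP call did not hold without Cebpg itself, which left 27. For thapsigargin in control cells they were the ATF4 and CHOP regulators, both amino acid lists, the synthetase list, both ER lists and the C/EBP list. For thapsigargin in knockdown cells they were the ATF4 and CHOP regulators, both ER lists, cholesterol synthesis and the C/EBP list. For the knockdown in thapsigargin they were the ATF4 and CHOP regulators, both amino acid lists, both ER lists, cholesterol synthesis and the C/EBP list. For the difference in response they were the ATF4 and CHOP regulators, both amino acid lists, both ER lists, the NRF2 list and cholesterol synthesis. The C/EBP list shares Atf3, Atf4, Atf5, Cebpb, Ddit3 and Jdp2 with the ATF4 and CHOP list, so calls of these lists are not independent. The C/EBP list was not tested without those shared members.

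The differences between knockdown and control cells were partly shared between treatments, as those of any lasting difference between the cell populations would be. In both treatments 2447 genes were higher, against 1128.2 by chance, and 2490 were lower, against 1192.5 by chance. Another 814 changed in opposite directions. Lce1g, Acta1, Serpinb9e and Prl2c2 were higher and Hp lower in both treatments, and Hmox1 was higher in DMSO (141 ± 10.4 against 53.2 ± 0.359 CPM) yet lower with thapsigargin (427 ± 18.6 against 644 ± 20.9 CPM). Across genes, the log2 changes of both treatments correlated with a Pearson r of 0.488 and a Spearman rho of 0.517.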

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

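The tests of library scaling, of a weaker response of every gene alike and of the amino acid ratio were chosen only after the result was seen. The values below stood out because the response to thapsigargin differed between the cell populations. It differed for 5598 genes, 2794 with a positive and 2804 with a negative difference. Of 2299 genes that rose, 553 had a negative and 115 a positive difference, with a median of -0.43. Of 1222 genes that fell, 84 had a negative and 443 a positive difference, with a median of 0.33.

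Among gene lists the median difference was -0.59 for the ATF4 and CHOP stress regulators, -0.75 for amino acid synthesis and one-carbon genes and -0.74 for amino acid transporters. It was -0.36 for cytosolic aminoacyl-tRNA synthetases, -0.63 for ER chaperones and -0.36 for ERAD and secretory pathway genes. It was -0.61 for glutathione and NRF2 genes, -0.44 for cholesterol synthesis and 0.36 for S phase and replication. It was -0.28 for the C/EBP and ATF family, -0.51 for the interferon response and -0.29 for the mitochondrial unfolded protein response. It was -0.066 for glycolysis and hypoxia and -0.39 for mitochondrially encoded mRNAs.

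Among genes the difference was -1.66 for Cebpg and -0.68 for Atf4. The positive extremes were Lrrc15 at 2.52, Cebpa at 2.20, Cxcl12 at 2.11, Csf2rb at 2.06, Pxylp1 at 2.04 and Cxcr6 at 1.87. The negative extremes were Avil at -4.88, Car6 at -4.29, Als2cl at -4.00, Cdsn at -3.93 and Lcn2 at -3.88. Icam1 had -4.23, but with 2 reads over the control DMSO group, under the floor of 3, its place among these is unknown. Stress regulators stood at -2.51 for Ppp1r15a, -2.22 for Ero1l, -1.82 for Atf3 and -1.66 for Sesn2. Amino acid synthesis stood at -2.20 for Cth, -1.33 for Got1, -1.05 for Phgdh and -0.96 for Psph. Transporters stood at -1.55 for Slc1a5, -1.21 for Slc7a1, -1.1 for Slc7a11 and -0.95 for Slc3a2. Synthetases stood at -0.89 for Wars, -0.88 for Gars and -0.84 for Eprs. ER genes stood at -1.17 for Pdia4, -1.05 for Hsp90b1, -0.92 for Dnajc3, -1.46 for Sel1l, -1.28 for Herpud1 and -0.94 for Syvn1. Hmox1 stood at -1.997, Gsta4 at -1.22, Ccne1 at 0.93, Mcm6 at 0.84 and Mvd at -1.08.

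The reads with no unique alignment were left out of the counts and so not analysed, and they were a larger share in knockdown cells. They made up 5.28% in DMSO and 4.53% with thapsigargin in knockdown cells, against 4.81% and 4.19% in control cells.

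The weaker rise of ER and amino acid genes in knockdown cells was weighed against 3 explanations. Library scaling was tested for the ER chaperones only, not for the degradation, secretory or amino acid genes. Among the 4 scalings tried none accounted for the weaker rise of the chaperones. Their median was -0.47 (-0.7 to -0.31) under the scaling that put it highest, a range from resampled list members, which are not independent. This test replaced one relative to all genes, which scaling cannot move. A strictly equal weakening of every gene was argued against. At least 7.6% of genes with an average response responded more strongly in knockdown cells at a one-sided p under 0.05. At most 5% was expected. Of 2 slope tests tried before, that of matrix genes gave 0.86 (0.7 to 1.13) against 0.72 (0.63 to 0.79) for ER chaperones. These ranges, from resampled list members, overlap, so that test could not tell the slopes apart and left an equal weakening open. The test of cholesterol genes, 1.03, was dropped since they were picked for their difference. A weaker response of induced genes in general might account for the weaker rise of ER and amino acid genes. It was not equal for all, as 115 of the 2299 genes with an average rise of at least 1 had a positive difference. The ratio of responses was 0.74 for the 23 ER genes with such a rise, against a random median of 0.79 (0.61 to 1.01). For the 18 amino acid genes with such a rise it was 0.66 against 0.75 (0.57 to 1). A selective loss at ATF4 and C/EBP gamma targets was therefore not set apart from a weaker response of induced genes in general.

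With 3 libraries against 3, 10 splits are too few for a share under 0.05. For the knockdown in DMSO the real value was 8154 genes and the highest other split 0, and for thapsigargin in control cells 11828 and 0. For thapsigargin in knockdown cells the real value was 11051 and the highest other 0, and for the knockdown in thapsigargin 9010 and 0. For the difference in response the real grouping, with 5598 genes, was the only 1 to reach that count among 100 splits drawn from 200, and the highest other was 4356. The split that exchanges knockdown and control in 1 treatment was not drawn. It would test the sum of both knockdown effects, and its count is unknown. Splits that keep the real labels in only 1 treatment carry the knockdown effect of that treatment. The count among splits therefore does not test the difference in response alone.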

How the results depend on the processing

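With library size only as the scaling, the difference in response gave 5205 positive and 1684 negative genes, since the median of all genes moved; among induced genes that rose 207 were positive with a median of -0.26, and among those that fell 45 were negative with a median of 0.49. With no low-count filter 4294 induced genes rose and with the stricter filter 1353, by construction. At an adjusted p under 0.01, 74 induced genes had a positive difference. Asking also for a log2 step of 1 left by construction 1410 genes (800 up, 610 down) for the knockdown in DMSO, 4169 (2556, 1613) for thapsigargin in control cells, 3096 (2085, 1011) in knockdown cells, 1747 (804, 943) for the knockdown in thapsigargin and 859 (305, 554) for the difference. Among induced genes that step left 334 negative and 39 positive of those that rose, and 14 negative and 99 positive of those that fell. Selecting induced genes on control cells alone gave 838 negative and 65 positive with a median of -0.60 among those that rose, and 38 and 779 with a median of 0.48 among those that fell. That selection biases the difference toward a weaker response in knockdown cells (regression to the mean). In simulated data with no difference it gave medians of -0.031 and 0.031. Selecting on an average of at least 2 gave 1165 that rose, with 230 negative, 24 positive and a median of -0.78, and 136 that fell, with 10, 43 and 0.50. An estimated correlation kept 28 of 78 list calls and 7 of 14 for the difference, and the cause of the losses was not tested. A higher correlation did not account for all of them. For thapsigargin in knockdown cells the epithelial call was lost (camera adjusted p = 0.0124, then 0.0851). Its estimated correlation, -0.038, lay below the preset 0.01. Replicate numbers did not pair, with 4 of 12 libraries closest to their own number, and a replicate block gave 2896 positive and 2875 negative differences. Taking Cebpg out of the C/EBP list, chosen after seeing the data, left 27 list calls with an estimated correlation. Removing GC or exon length trends, chosen after seeing the data, gave 2921 and 2963 positive differences. Leaving out 1 library gave 5062 to 5446 genes for the difference.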

Other observations

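Further gene groups were tested for the knockdown in DMSO. Amino acid transporters fell in 6 of 13 cases and rose in 0, also adjusted over the list alone (camera adjusted p = 0.00744, but adjusted p = 0.239 with an estimated correlation), with Slc6a9 falling from 14.8 ± 1.96 to 4.94 ± 0.423 CPM. ER-associated degradation and secretory pathway genes fell in 13 of 22 cases and rose in 1, also adjusted over the list alone (camera adjusted p = 0.0074, but adjusted p = 0.112 with an estimated correlation), with the translocon gene Ssr3 falling from 753 ± 15.2 to 549 ± 15.6 CPM. Cholesterol synthesis genes fell in 14 of 20 cases and rose in 2, also adjusted over the list alone (camera adjusted p = 0.00981, but adjusted p = 0.23 with an estimated correlation), with Fdps falling from 4.98 ± 0.258 to 2.19 ± 0.26 CPM. Messenger RNAs of mitochondrial DNA rose in 6 of 10 cases and fell in 0, or 7 and 0 adjusted over the list alone (camera adjusted p = 0.0172, but adjusted p = 0.417 with an estimated correlation), mt-Nd1 going from 2426 ± 42.3 to 3817 ± 261 CPM. Cytosolic ribosomal protein genes rose in 15 of 30 cases and fell in 0, also adjusted over the list alone (camera adjusted p = 0.0154, but adjusted p = 0.681 with an estimated correlation), with Rps2 at 377 ± 23.7 and 524 ± 32.7 CPM. The ribosomal call was also lost without knockdown DMSO replicate 2 (adjusted p = 0.0524, in a range of 7.49e-05 to 0.681 over its alternatives). Glycolysis and hypoxia genes fell in 8 of 19 cases and rose in 5, also adjusted over the list alone (camera adjusted p = 0.0462, but adjusted p = 0.367 with an estimated correlation), with Pdk1 falling from 79.0 ± 3.35 to 28.4 ± 1.67 CPM. That call was also lost under RLE size factors (adjusted p = 0.0523), upper-quartile scaling (0.0599), the stricter filter (0.088), only the compared groups (0.0537) and limma-voom (0.139), and without control DMSO replicate 2 (0.054), knockdown DMSO replicate 1 (0.0763) or knockdown DMSO replicate 3 (0.0797), in a range of 0.000109 to 0.367 over its alternatives. Inflammatory genes went both ways, 9 of 17 up and 5 down, also adjusted over the list alone (camera adjusted p = 0.223), with Ptgs2, the inducible cyclooxygenase, rising from 168 ± 24.1 to 671 ± 26.1 CPM. Of 5 adipocyte markers 2 rose and 2 fell, or 2 and 3 adjusted over the list alone (camera adjusted p = 0.551), and of 17 autophagy genes 3 rose and 7 fell, also adjusted over the list alone (camera adjusted p = 0.499).

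With thapsigargin in control cells p53 targets rose in 10 of 17 cases and fell in 3, also adjusted over the list alone (camera adjusted p = 0.00075, but adjusted p = 0.145 with an estimated correlation), with Plk2 going from 180 ± 10.2 to 852 ± 30.2 CPM. Mitochondrial unfolded protein response genes rose in 7 of 11 cases and fell in 2, also adjusted over the list alone (camera adjusted p = 0.0172, but adjusted p = 0.271 with an estimated correlation), with the protease gene Lonp1 going from 140 ± 3.44 to 452 ± 8.56 CPM. That call was also lost with limma-voom (adjusted p = 0.0598, in a range of 1.36e-07 to 0.271 over its alternatives). Cxcl2 and Krt18 had 0 reads in the control DMSO group and were at least 38.8-fold and at least 49.8-fold higher with thapsigargin, and the von Willebrand factor gene Vwf rose from 0.28 ± 0.0625 to 4.35 ± 0.678 CPM. Of 4 leukocyte markers tested 2 rose and 1 fell, also adjusted over the list alone, Cd74 going from 2.24 ± 0.379 to 18.3 ± 0.977 CPM. Autophagy genes rose in 7 of 17 cases and fell in 7, also adjusted over the list alone (camera adjusted p = 0.382), Sqstm1 going from 628 ± 40.8 to 2537 ± 12.7 CPM. Adipocyte markers had a median of -1.01 while camera pointed up (adjusted p = 0.868). In knockdown cells given thapsigargin, G2 and mitosis genes fell in 16 of 18 cases (camera adjusted p = 3.31e-05, but adjusted p = 0.127 with an estimated correlation). Under thapsigargin the knockdown cells held higher levels of 14 of 17 p53 targets and lower levels of 2, or 15 and 2 adjusted over the list alone (camera adjusted p = 0.000232, but adjusted p = 0.112 with an estimated correlation), and of 9 of 17 immediate early genes, with 6 lower, or 10 and 6 adjusted over the list alone (camera adjusted p = 0.00981, but adjusted p = 0.358 with an estimated correlation). The immediate early call was also lost with limma-voom (adjusted p = 0.0604, in a range of 9.36e-05 to 0.358 over its alternatives).

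Genes silent in DMSO, with a mean of at most 0.03 CPM over its libraries, gained reads with thapsigargin, and the test of library size and the reverse selection were chosen after the result was seen. Their summed level was 75.4 ± 4.9 CPM in control DMSO and 589.4 ± 48.8 CPM in control thapsigargin libraries, and 111.7 ± 9.8 and 651.4 ± 47.7 CPM in the knockdown libraries, a contrast widened by selecting on DMSO; genes silent by that rule with thapsigargin stood at 89.3 ± 5.6 and 94 ± 3 CPM in control and 117.8 ± 5.4 and 120.7 ± 12.6 CPM in knockdown libraries. Library size did not account for it, since after thinning all libraries alike the smaller difference in genes detected was still 2700. Genomic DNA as the sole source was argued against, because 47.7% of the gained reads lay in the 1% of silent genes with the largest gain. A share of genomic DNA among the other gained reads was not excluded, since gene length was not used. Read-through from a neighbour could not be told apart from other sources, the odds ratio being 1.43 (1.09 to 1.88) for a neighbour whose 3' end faces the gene and 1.27 (0.96 to 1.67) for one whose 5' end does.

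Neighbouring genes rose together in knockdown cells in DMSO, and the rule for calling the paralog test open was set after its result was seen. Neighbours were consecutive on a chromosome among the 13508 protein-coding genes tested. There was no limit on their distance, and genes not tested can lie between them. Adjacent risen pairs numbered 78, against a median of 30 and a range of 17 to 48 in 1000 shuffles, so chance adjacency was put aside. With pairs of one family removed 45 remained, against a median of 26 and a range of 12 to 47, and 1 of the shuffles held as many. By the rule written beforehand a number under the highest shuffle counted for reads shared between near-identical paralogs; by the rule set later the test was left open. A gain of chromosome copies that reached 1 Mb around most such pairs was argued against. Other genes within that distance had a median log2 change of 0 over 923 genes. All pairs were pooled, so a narrower gain, or one at a few places, was not excluded. Libraries read at the genomic level, or long reads over the Serpinb9, Prl2c and Lce1 clusters, would tell these apart.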
